A study of Arabidopsis thaliana with 4 samples.

How the data were processed

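The series measured the 5′ ends of uncapped, polyadenylated RNA fragments (the degradome) in wild-type Arabidopsis thaliana. Per the labels' protocols, total RNA was extracted with Trizol and poly(A)+ RNA was selected on oligo(dT) beads before libraries of 20 or 21 nt tags were made. A tag marks the first nucleotides downstream of the point where an RNA was cleaved or where its decay had stopped. Of the 4 libraries, library 1 (inflorescence, sequenced by pyrosequencing) was not analysed here. Library 2 came from inflorescence, was primed with dT and was amplified as a pool. Library 3 came from inflorescence and library 4 from seedlings, and both were randomly primed with primer extension. Each group held 1 library, and the numbered runs of a library were repeat sequencing of that library, so their spread was technical.

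The deposited files gave, for each run, every distinct read and its count, and the authors had applied no normalization to these counts that the sources used here record. Filters, base caller and genome build were not given in the sources used here. The reads still held adapter sequence. Each was read as the reverse complement of a 20 or 21 nt tag followed by GTTGGA, the start of the adapter. A read with that sequence after 20 or 21 nt and no undetermined base in the tag gave 1 tag. Between 20.4% and 53.4% of the reads of a run gave a tag. Reads that started with a run of T made up between 37.4% and 43.5% of the runs of library 2. Lines that held a read name in place of a sequence, at most 56 per run, were left out.

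Runs 5 and 7 of library 3 shared 86.6% of the sequences seen once, and runs 6 and 8 of library 4 shared 87.1%, whereas other pairs of runs shared between 10.7% and 22.9%. Of the stray read names, 33 of 37 and 41 of 46 were also the same. These pairs differed by less than sampling noise, so each was counted as 1 run and runs 7 and 8 were left out. The plan made before the data were examined had summed all runs. That sum was kept as an alternative. This left 3 runs of library 2 with 1305121 tags, 4 runs of library 3 with 5020196 tags and 4 runs of library 4 with 3942603 tags.

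Tags were matched without mismatch to the RefSeq transcripts and chromosomes of Arabidopsis thaliana, assembly TAIR10.1. All coordinates are 1-based positions on that assembly. A tag counted in full at each transcript position it matched in the sense direction, for target sites and positions. For genes, only tags of 1 nuclear protein-coding gene counted, which gave 848998 tags in library 2, 1561338 in library 3 and 1349255 in library 4, and counts were scaled to CPM of these totals. Ratios between libraries were log2 ratios of CPM + 1. A start is a distinct transcript position with at least 1 tag.

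Target sites of miRNAs and of trans-acting siRNAs (tasiRNAs) came from a list of 148 guide and gene pairs fixed before the data were examined. Each guide family was aligned without gaps to the gene's representative transcript, and the best site with an Allen score of at most 7 was kept, where a mismatch scores 1, a G:U pair 0.5, and both double at guide nucleotides 2 to 13. This gave 137 sites. The other 11 pairs gave no site, among them DCL1 with miR162, CSD2 with miR398, LAC7 with miR857, AT1G64580 with miR161.2 and 7 GRF genes with miR396. The slice position is the transcript nucleotide opposite guide nucleotide 10. A site was at the transcript maximum where no other position of the transcript had more tags than the slice position. The count of such sites was set against 10000 draws of random positions on the same transcripts, with a one-sided p. The slice share is the percentage of a transcript's tags that lay at the slice position, with an exact Clopper-Pearson 95% interval. Slice tags were compared between libraries 3 and 4 relative to all nuclear coding tags, of which there were 1647488 and 1421661, with exact conditional 95% intervals of the ratio.

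A search of all transcripts used 353 annotated guides in 295 families. It kept positions that were the maximum of their transcript with at least 2 tags and an alignment score of at most 4, and was repeated with 100 sets of shuffled guides. Tag positions were given as a percentage of transcript length on nuclear protein-coding transcripts. Genes with at least 10 CPM in 1 of the 2 libraries compared were called higher or lower at a 4-fold ratio. Gene lists fixed before the data were examined covered floral organ identity, anther and pollen, seed storage and embryo, root, photosynthesis, meiosis, cell cycle and circadian clock. Lists of cytosolic ribosomal proteins and core histones were taken from the wording of the annotated product, and the fixed miRNA target genes formed another. A list's median was given as a percentile among 10000 random lists of the same size, matched on mean log2 CPM in 20 bins. Libraries 3 and 4 differ in tissue, and libraries 2 and 3 in preparation. Libraries 2 and 4 differ in both and were not compared.

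With 1 library per group, no difference between groups has a replicate check, no p-value across genes was computed, and a ratio of 2 libraries compares those libraries, not the conditions. The number of run pairs with the same direction shows the repeatability of sequencing only. A count of 0 was replaced by a floor of 3 counts in the library concerned, which was 3.53 CPM in library 2, 1.92 CPM in library 3 and 2.22 CPM in library 4. A fold of at least a value, given where 1 library had 0 tags, sets the 0 to that floor. It leaves out the counting error of the other library, so it is not a confidence limit. Intervals cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

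The genes named in the text followed a rule fixed before the data were examined. Among target sites at the transcript maximum, the 12 with most slice tags over the 3 libraries were named, with at most 2 per guide family, then the site with most slice tags of every other guide family, and every site with at least 10 slice tags in library 3 or 4 and a 4-fold ratio between them. For each gene comparison the 12 largest ratios in each direction were named among genes with at least 50 CPM in the higher library and 1 direction in every pair of runs, and up to 4 members of each list at its extremes. From the search, the 8 positions outside the fixed pairs with most tags were named. Genes named beyond this rule are said to have been chosen after their values were seen.

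Alternatives were other slice positions, windows, score limits, tag minimums, shuffles and multiple-match rules, another weighting of genes and starts, other CPM minimums, a pseudocount of 5, median-of-ratios size factors, the last 500 nt of transcripts, and leaving out each run in turn. Alternatives added after the data were seen were the repeated runs included, starts tagged in both libraries left out, starts that follow TCCAAC left out, and guides that repeat 3 nt left out. The scripts were tested on simulated data with known changes. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9 were used.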

Results

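The degradome of wild-type Arabidopsis was sampled to detect RNAs cleaved under the direction of miRNAs and siRNAs, using tags from the 5′ ends of uncapped, polyadenylated RNA. Library 2 (inflorescence, dT primed) held 1305121 tags, library 3 (inflorescence, random primed) 5020196 tags and library 4 (seedlings, random primed) 3942603 tags, with 1 library per group and no replicate plants. Nuclear protein-coding transcripts took 68.0% of the tags of library 2, 32.8% of library 3 and 36.1% of library 4. Ribosomal RNA took 0.34%, 19.2% and 15.5%, and the organelle genomes 0.227%, 11.5% and 9.48%. Among tags that matched coding transcripts in 1 direction, 99.3%, 98.1% and 98.2% were in the sense direction.

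Cleavage at miRNA and tasiRNA target sites was compared with the other tags of the same transcripts. ARF17, an auxin response factor targeted by miR160, had the most slice tags in library 3 and in the sum of the 3 libraries, and 84.6% of its tags in library 3 lay at the single nucleotide opposite guide nucleotide 10 (296 of 350, 95% interval 80.4% to 88.2%). The share was 76.5% in seedlings (75 of 98, 66.9% to 84.5%) and 38.1% in library 2 (16 of 42, 23.6% to 54.4%). HAM3 and HAM2, GRAS transcription factors targeted by miR171 that act in the shoot meristem, had shares of 50.9% (55 of 108, 41.1% to 60.7%) and 48.7% (57 of 117, 39.4% to 58.1%) in library 3. In seedlings HAM3 reached 66.5% (105 of 158, 58.5% to 73.8%) and HAM2 26.9% (18 of 67, 16.8% to 39.1%). Library 2 held 3 slice tags among 17 for HAM3 and 0 among 22 for HAM2, where the interval reached 15.4%. The ARF17 site spans positions 29274189 to 29274209 of chromosome 1 in coding exon 2 of 2, that of HAM3 58411 to 58431 of chromosome 4, and that of HAM2 22411544 to 22411564 of chromosome 3, both in the coding part of the only exon.

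The noncoding tasiRNA precursors TAS1C and TAS2 carried slice tags at their miR173 sites, from 16537890 to 16537911 and from 16539991 to 16540012 of chromosome 2. TAS1C had 39.0% of its tags there in library 2 (16 of 41, 24.2% to 55.5%), 60.5% in library 3 (78 of 129, 51.5% to 69.0%) and 53.0% in seedlings (35 of 66, 40.3% to 65.4%). TAS2 had 6.70% (13 of 194, 3.62% to 11.2%), 28.0% (66 of 236, 22.3% to 34.2%) and 15.1% (38 of 252, 10.9% to 20.11%), and its slice position was not the maximum in seedlings. AGO2, an Argonaute protein with a miR403 site in its 3′ UTR (chromosome 1, 11185223 to 11185243, exon 3 of 3), had 58.8% in library 2 (47 of 80, 47.2% to 69.6%), 51.8% in library 3 (58 of 112, 42.1% to 61.3%) and 33.96% in seedlings (18 of 53, 21.5% to 48.3%).

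SPL5 and SPL11, transcription factors of the vegetative phase change that are targets of miR156, had seedling shares of 38.6% (27 of 70, 27.2% to 51.0%) and 54.1% (20 of 37, 36.9% to 70.5%), and library 3 shares of 29.4% (20 of 68) and 21.7% (13 of 60). The floral regulator AP2 had 52.2% of its seedling tags at the miR172 site (12 of 23, 30.6% to 73.2%) and 27.7% in library 3 (18 of 65, 17.3% to 40.2%). AFB3, an auxin receptor F-box protein, had 48.1% in seedlings (13 of 27) and 26.2% in library 3 (11 of 42) at the miR393 site. PHB, a class III HD-ZIP regulator of leaf polarity, had 12.6% in library 3 (32 of 254) and 10.8% in seedlings (18 of 166) at the miR166 site, with a tag that 2 genes share, and 3.54% and 1.33% when tags shared by genes were left out. AT4G29770, a target of a tasiRNA of the TAS1 family, had 83.3% of its tags at the site in seedlings (20 of 24, 62.6% to 95.3%) against 18.2% in library 3 (8 of 44, 8.19% to 32.7%), or 100% against 53.3% without tags shared by genes. The SPL5 site lies in the 3′ UTR (chromosome 3, 5140598 to 5140617). The others lie in coding exons: SPL11 (chromosome 1, 9503618 to 9503637), AP2 (chromosome 4, 17403019 to 17403039), AFB3 (chromosome 1, 4369085 to 4369106), PHB (chromosome 2, 14642530 to 14642666, across an intron) and AT4G29770 (chromosome 4, 14577245 to 14577265). AT5G18040, another TAS1 siRNA target, chosen after its values were seen, had 24, 43 and 38 slice tags in libraries 2, 3 and 4 but more tags at another position.

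**Figure D1:**
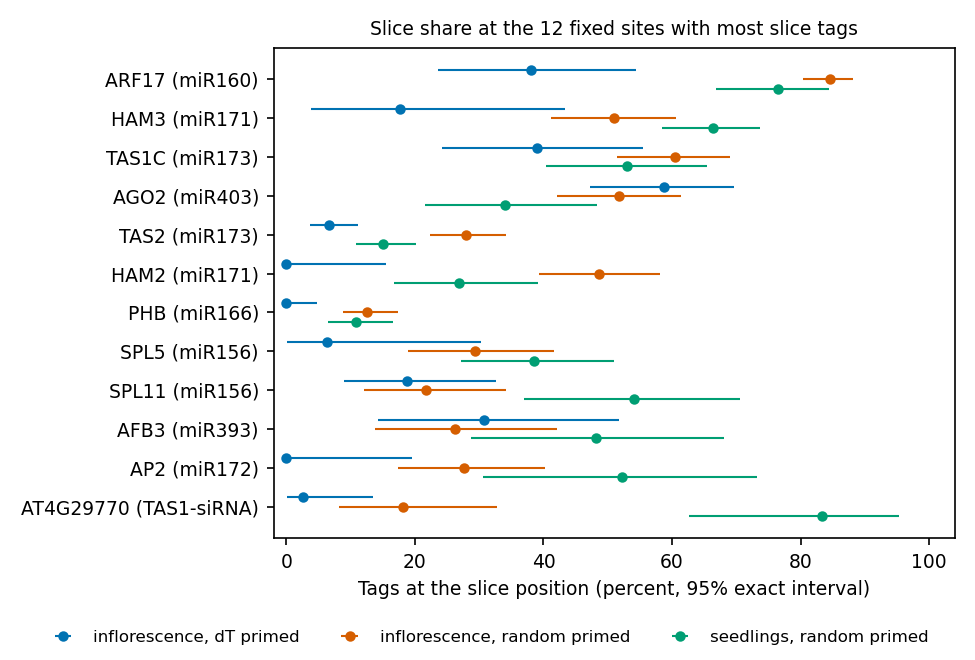
Share of each transcript's tags at the slice position (x axis, percent) for the 12 fixed sites with most slice tags among those at the transcript maximum in a library, at most 2 per guide family (y axis, gene and guide), with 95% exact intervals as bars and 1 colour per library. ARF17 had the highest share of the inflorescence, random primed library at 84.6% and AT4G29770 the highest of the seedling library at 83.3%.

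Between inflorescence and seedlings, both random primed, slice tags, scaled to all coding tags, differed in both directions. The miR160 targets ARF17 and ARF16 had 3.41-fold (95% interval 2.64 to 4.45) and 4.53-fold (1.53 to 18.2) fewer slice tags in seedlings, where ARF16 had 4 against 21. Another miR160 target, ARF10, chosen after its values were seen, had 18 slice tags in library 3 and 17 in seedlings. AGO2 had 2.78-fold fewer in seedlings (1.62 to 5.01), HAM2 2.73-fold fewer (1.58 to 4.93) and TAS1C 1.92-fold fewer (1.28 to 2.95). TOE2, an AP2-related repressor of flowering with a miR172 site that shares its tag with a noncoding RNA, had 4.53-fold fewer (1.53 to 18.2). MYB111, an activator of flavonol synthesis with a miR858 site, had 19 slice tags in library 3 and 0 in seedlings, 5.47-fold lower with the 0 at the floor. NLA, a ubiquitin ligase with a miR827 site in its 5′ UTR, had 13 against 2, a 5.61-fold lower value (1.27 to 51.2). HAM3 and AT4G29770 went the other way, at 2.21-fold (1.58 to 3.12) and 2.90-fold (1.22 to 7.60) more slice tags in seedlings. For TAS2, PHB, SPL5, SPL11, AFB3 and AP2 the interval of the ratio included no difference. Over all coding tags of the seedling library, 78.6% lay at starts that library 3 had tagged too. The seedling shares and ratios were not corrected for molecules that the libraries may share.

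The best sites of the other guide families held fewer slice tags. TCP4, a leaf growth regulator targeted by miR319, had 16 of 133 tags at the site in library 3 and 8 of 28 in seedlings, and the tasiRNA precursor TAS3C had 15 of 41 and 5 of 15 at its miR390 site. MYB65 with miR159, whose tag 2 genes share, had 3 of 45 and 10 of 59, and AT1G63330 with miR161.2, whose tag 4 genes share, had 2 of 30 and 7 of 35. TAS4 with miR828 had 6 of 6 and 0 of 2, the DNA methyltransferase CMT3 with miR823 had 7 of 153 and 0 of 69, and AGL16 with miR824, whose tag 2 genes share, had 5 of 23 and 0 of 9. With the 0 set to the floor of 3 counts, CMT3, TAS4 and AGL16 were 2.01-fold, 1.73-fold and 1.44-fold lower in seedlings. These folds leave out the counting error of library 3, and for AGL16 the exact interval of the ratio included no difference. AGO1 with miR168 had 6 of 1281 and 2 of 824. Sites with at most 4 slice tags, in 1 of these libraries only, included SULTR2;1 with miR395 and ORE1 with miR164, with 4 in seedlings. AT1G06580 with miR400 and CSD1 with miR398 had 3 and UCC2 with miR408 had 2, also in seedlings, and bHLH74 with miR396 and IAR3 with miR167 had 1 in library 3. NF-YA8 with miR169 had 1 and 2, and LCR with miR394 had 1 tag, in library 2. No aligned site of the TAS3 siRNAs, miR161.1, miR163, miR397, miR399, miR447 or miR472 had a slice tag in libraries 2, 3 or 4. Nor did the sites of miR773, miR780, miR834, miR846 and miR859. For TCP4, TAS3C, MYB65, AT1G63330, AGO1 and NF-YA8 a difference between the tissues was not detectable at this depth, since the interval of the ratio included no difference.

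Of the 137 fixed sites, 52 had a slice tag in library 3, 50 in library 4 and 28 in library 2. The slice position was the transcript maximum at 22 of 116 sites whose transcript had tags in library 3, 20 of 122 in library 4 and 16 of 123 in library 2. Random positions on the same transcripts gave means of 0.0724, 0.0792 and 0.1002 such sites and at most 2, 3 and 3 in 10000 draws, a one-sided randomisation p of 0.0001 in each library, which is the smallest these draws can give. The slice positions held 9.50% of the tags of these transcripts in library 3 (1105 of 11626, 8.98% to 10.1%), 8.64% in library 4 (669 of 7743, 8.02% to 9.29%) and 3.18% in library 2 (177 of 5560, 2.74% to 3.68%). These shares depend on where a library's tags lie. The last 500 nt of coding transcripts held 88.6% of the tags of library 2, 66.9% of library 3 and 75.3% of library 4. A lower share in library 2 therefore does not show less cleavage. Opposite guide nucleotide 9 the counts of sites at the maximum were 4, 0 and 0, and opposite guide nucleotide 11 they were 1, 1 and 0. In simulated tags, 40 of 40 planted sites were recovered and random tags put 1 of 137 sites at the maximum. Planted sites were given a far larger share of tags than slice positions held here over all sites, with the other tags spread evenly. Their recovery therefore does not measure sensitivity at the shares seen.

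**Figure D2:**
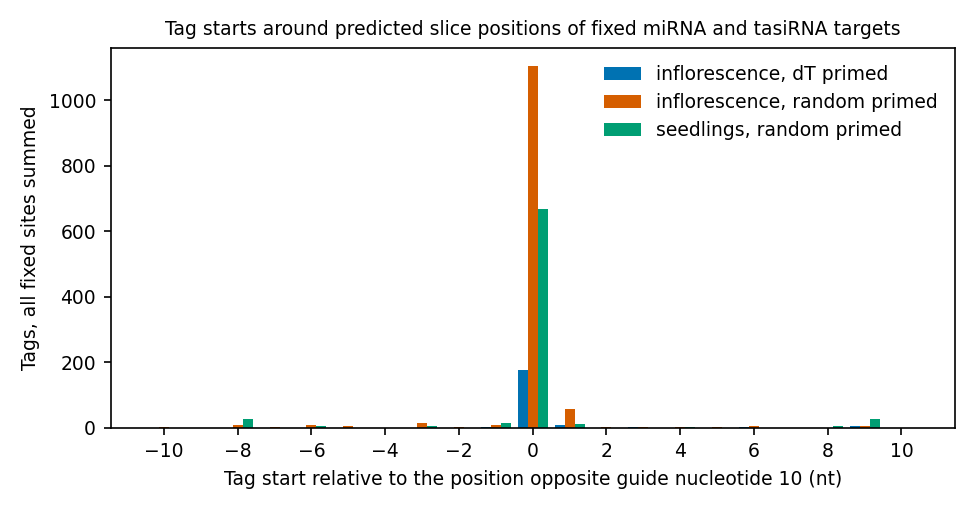
Tags summed over all fixed sites (y axis, tags) by distance of the tag start from the nucleotide opposite guide nucleotide 10 (x axis, nt), with 1 bar colour per library. The bars at 0 stand for 177, 1105 and 669 tags in libraries 2, 3 and 4.

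The search of all transcripts, which took in the fixed pairs, returned mostly repeats. Of the matches found in libraries 2, 3 and 4 (395, 251 and 236), all but 17, 34 and 31 belonged to miR414, miR5021 and miR5658, guides of which at least 70% repeat 3 nt. The positions named by rule were of this kind. A single tag shared by 17 genes (10, 45 and 27 tags) was the maximum of the transcripts of NAF1, ULP1D, AT1G63980, AT2G21420, AT3G17160, AT5G23950 and AT5G55580 opposite miR414 in both inflorescence libraries, and in seedlings for all of these but AT1G63980 and AT3G17160. Tags shared by 255 genes (4, 22 and 15 tags) were the maximum of the clock gene LHY opposite miR5021. Among matches of other guides outside the fixed pairs, chosen after their values were seen, AGO3, the neighbour of AGO2, had 16 of its 28 seedling tags at a miR403 site of score 3 in its 3′ UTR (chromosome 1, position 11192410), with 2 of 4 in library 2 and 1 of 7 in library 3. The noncoding RNA AT3G08845 had 21 of 28 tags in library 3 and 4 of 8 in seedlings at a miR172 site, with the same tag as TOE2. AT5G41170, a pentatricopeptide repeat gene, had 7 of 7 seedling tags and 2 of 2 in library 3 at a miR161.2 site whose tag 4 genes share. The fixed miR161.2 target AT1G63330 had as many slice tags in both libraries, so these may be the same reads.

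Shuffled guides gave means of 0.540, 0.740 and 0.360 matches, so real guides gave 731, 339 and 656 times as many in libraries 2, 3 and 4, with a one-sided randomisation p of 0.0099, the smallest 100 shuffles can give. Leaving out 1 run, with fewer shuffles, gave 170 to 1120, 301 to 352 and 770 to 1140. Without the 3 repeat guides, an alternative added after the data were seen, these ratios were 53.1, 100 and 119. They were 48.8, 96.6 and 92.6 with tags of 1 gene only, and 10.98, 46.6 and 39.9 with shuffles that keep dinucleotides and 1 guide per family. In simulated tags the search recovered 34 of 34 planted sites, which held the same large shares of tags, so sensitivity at the shares seen was not measured.

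Tags lay toward the 3′ end of transcripts in all 3 libraries, and most strongly in library 2, dT primed. The 3′ UTRs of nuclear genes, 17.9% of the length of the tagged transcripts in library 2, held 74.8% of its tags, against 50.7% in library 3 and 59.9% in seedlings. Coding sequences held 24.7%, 46.9% and 37.8%, and 5′ UTRs 0.427%, 2.41% and 2.33%. The median tag lay at 82.7% ± 0.315 of transcript length in library 2 (SD, n = 3 runs), 75.5% ± 0.725 in library 3 (SD, n = 4 runs) and 78.9% ± 0.650 in library 4 (SD, n = 4 runs). The runs repeat the sequencing of 1 library, so their spread does not test differences between libraries. The last 500 nt of transcripts held 88.6%, 66.9% and 75.3% of the tags. With each start counted once the medians were 84.2%, 65.6% and 68.7%, which widened the gap between library 2 and the others. Starts tagged in both random primed libraries lay at a median of 80.8% in seedlings, and seedling starts not tagged in library 3 at 64.4%.

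**Figure D3:**
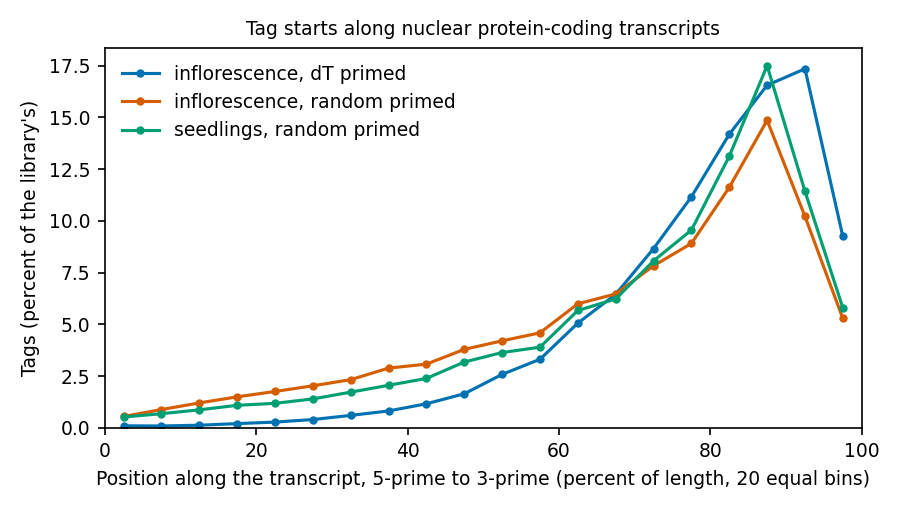
Percentage of each library's tags (y axis) in 20 equal bins along nuclear protein-coding transcripts from the 5′ to the 3′ end (x axis, percent of length). Lines with points stand for the 3 libraries, with medians at 82.7% (dT primed), 75.5% and 78.9% (random primed inflorescence and seedlings).

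Seedlings and inflorescence, both random primed, were compared gene by gene for differences between the tissues. PYK10, a beta-glucosidase of endoplasmic reticulum bodies (AT3G09260, chromosome 3, 2840477 to 2843781), had 1688 tags from 427 starts in seedlings and 0 in library 3, at least 651-fold higher. The jacalin-related lectin genes JAL22, JAL33 and JAL34 were at least 124-fold, 95.3-fold and 66.0-fold higher, whereas JAL23, chosen after its values were seen, had a log2 ratio of -1.47 (range over run pairs -1.73 to -1.25). PBP1, which binds PYK10, had 837 tags against 5, a log2 ratio of 7.21 (range over run pairs 5.70 to 9.38). MLP34, a major latex protein relative, had 837 tags against 1 (ratio 969, 95% interval 173 to 38301), and CYP81F4, an enzyme of indole glucosinolate synthesis, had 328 against 1 (380, 67.6 to 15037). DR4, GRP9 and CYP705A5 were at least 110-fold, 62.5-fold and 55.2-fold higher. The iron-deficiency regulator BHLH100 and the proline-rich protein PRP1 were at least 66.3-fold and 52.1-fold higher, but 98.8% and 83.7% of their seedling tags lay at 1 start each, and 98.8% of those of BHLH100 followed TCCAAC in the transcript.

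Among the genes lower in seedlings, E13L3, a glucan endo-1,3-beta-glucosidase-like protein (AT5G08000, chromosome 5, 2563366 to 2565547), had 0 tags against 201, at least 57.9-fold lower, and the homeobox gene HB-3 0 against 86, at least 24.8-fold lower. The formin FH3 had 1 tag against 109 (94.2-fold lower, 16.6 to 3754), AT5G61720 2 against 89 (38.5-fold, 10.3 to 322), the midasin-like AT1G67120 3 against 109 (31.4-fold, 10.5 to 155) and CYP98A9, a cytochrome P450, 2 against 83 (35.9-fold, 9.62 to 301). The leucine-rich repeat genes AT3G19020 and AT1G49490 had log2 ratios of -5.06 (range over run pairs -6.61 to -4.11) and -4.91 (-7.15 to -4.00). EXL4, a lipase of the pollen coat, had -3.86 (-5.12 to -2.92), the glycan synthase CSLA01 -3.64 (-4.07 to -3.29), AT2G23910 -3.61 (-5.88 to -2.57) and HCAR, a reductase of the chlorophyll cycle, -3.60 (-3.89 to -3.17). In library 3, tags after TCCAAC made up 85.2% of the tags of AT3G19020, 72.4% of AT1G49490, 60.2% of CYP98A9, 50.7% of E13L3, 38.4% of HB-3 and 37.5% of CSLA01.

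Of the 50 photosynthesis genes, all measured, 47 were higher in seedlings, with a median log2 ratio of 0.68 that lay at percentile 100 of the random lists. PSBO2 of the oxygen-evolving complex (2.42, 2.11 to 3.24 over run pairs) and the small Rubisco subunit RBCS2B (1.70, 1.52 to 1.84) led the list, and the electron transport genes FNR1 (-0.21, -0.44 to 0.00) and PETC (-0.04, -0.21 to 0.18) were its lowest. For RBCS2B 54.3% of the seedling tags lay at 1 start, against 7.44% in library 3, and the log2 ratio of starts was 0.80. For PSBO2 35.1% of the seedling tags and 21.0% of those of library 3 followed TCCAAC, and the log2 ratio of starts was 2.24. Of 12 seed storage and embryo genes 4 were measured, none with a tag in library 3. The cruciferins CRA1 and CRU3, the oleosin OLEO2 and the embryo regulator ABI3 were at least 19.7-fold, 19.3-fold, 8.49-fold and 6.94-fold higher in seedlings. Their median log2 ratio was 4.68, or 3.68 with the zeros at the floor, at percentile 99.98, and 72.2% of the ABI3 tags followed TCCAAC.

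Floral genes were lower in seedlings and yet tagged there. All 12 measured floral organ identity genes were lower, PI only without size factors, with a median log2 ratio of -0.79 at percentile 1.83. SEP4 and SHP2 had 0 seedling tags, at least 6.91-fold and 7.20-fold lower, whereas the petal and stamen identity gene PI had 799 against 1090 (log2 ratio -0.24, -0.52 to -0.12 over run pairs) and the ovule gene STK 20 against 29. Of 17 measured anther and pollen genes 14 were lower, with a median of -1.11 at percentile 0.550. The tapetum regulator AMS and the sporopollenin synthesis gene LAP5 had 0 seedling tags, at least 6.63-fold and 16.7-fold lower, while BCP1 had 112 against 123 and TDF1 15 against 4, at 1 start in each library. Of the seedling tags of the anther and pollen list 97.0% lay at starts that library 3 had tagged too and 56.5% at starts that library 2 had tagged. These values were 98.3% and 80.1% for the floral organ list, and 78.6% and 53.4% over all genes. With each start counted once the medians of the floral organ, anther and pollen, and photosynthesis lists were -1.86, -2.35 and 1.15.

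**Figure D4:**
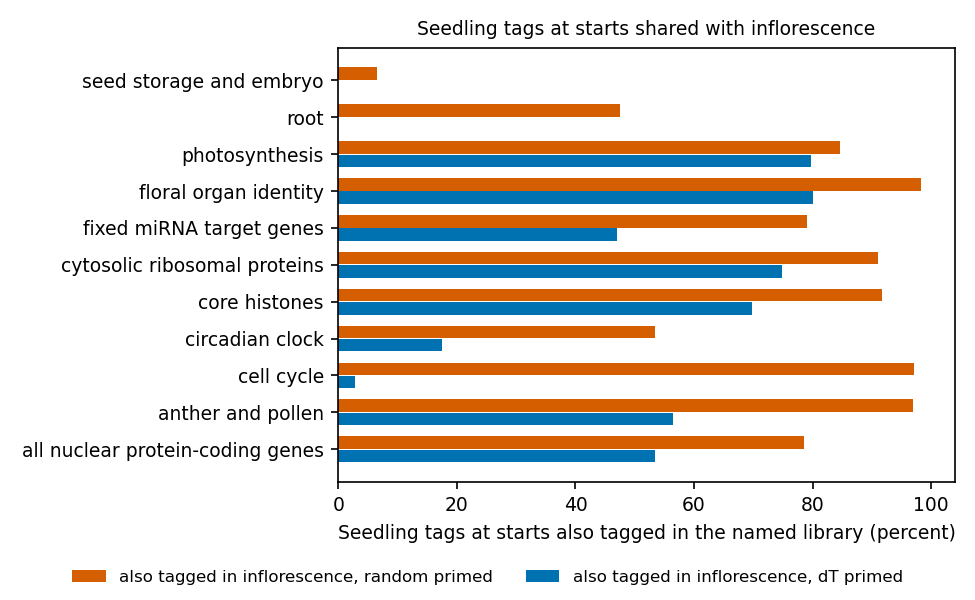
Percentage of seedling tags (x axis) of each gene list (y axis) at transcript positions where the inflorescence libraries also had a tag, with 1 bar colour per inflorescence library. For the anther and pollen list the bars reach 97.0% (random primed) and 56.5% (dT primed), and for all nuclear protein-coding genes 78.6% and 53.4%.

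Cytosolic ribosomal proteins had a median log2 ratio of -0.21 with 191 of 268 members lower (percentile 0.0300). With size factors, which raise all genes alike, the median was 0.076 and its percentile 0.01. The members at the ends of this list, AT1G53560 (2.74) and AT3G09680 (1.12) above, AT2G45710 (-3.29) and AT3G06320 (0 tags, at least 5.47-fold lower) below, were taken in by the family name of their annotated product. The fixed miRNA target genes had -0.43 with 60 of 87 lower (percentile 3.97), from RAP2.7 (0 tags in library 3, at least 5.79-fold higher) and UCC2 (2.51) to SPL4 (-2.97) and GRF8 (-3.93). Cell cycle genes had -0.61 with 6 of 9 lower (percentile 17.2), or -1.24 (percentile 0.5) with each start counted once, and CDKB2;2 (-3.14) and MAD2 (-2.36) lay lowest. AUR1, a mitotic kinase, had 99.9% of its 1702 seedling tags and 98.1% of its 1576 tags in library 3 at a single start. Core histones had -0.34 with 10 of 13 lower (percentile 22.2), a list that the wording of the annotation extends to the SET7/9 family genes AT1G77660 (0.40) and AT4G17080 (-2.10). Circadian clock genes had -0.25 with 5 of 7 lower (percentile 52.9) and 0.03 with size factors, from CCA1 (1.26) to ELF4 (-2.99). Of 15 root genes 4 were measured, with a median of 0.28 (percentile 88.3), or 0.80 (percentile 97.99) at a minimum of 1 CPM and 2.04 (percentile 99.5) with each start counted once, and values from IRT1 (0.85) to SHR (-0.78). None of the 7 meiosis genes was measured.

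Over 12598 measured genes, 384 were at least 4-fold higher and 951 at least 4-fold lower in seedlings, and 367 and 901 of these kept their direction in all 16 pairs of runs. The median log2 ratio of all genes was -0.25. Size factors moved it up by 0.27, with which 486 genes were higher and 665 lower, and PI, PETC and FNR1, whose ratios lay nearer to 0 than this shift, changed sign. The correlation of log2 CPM across genes, which are not independent replicates, was 0.727, against 0.886 to 0.910 between runs of library 3 and 0.871 to 0.885 between runs of library 4. Counts of genes depended on the treatment of low counts and of heavily tagged starts: 171 higher and 292 lower at a minimum of 25 CPM, 185 and 261 with a pseudocount of 5, and 1146 and 1235 with each start counted once. In simulated libraries 98.0% of genes changed 6-fold and 100% of those changed 12-fold were recovered, with 4 of 11493 unchanged genes called. The simulation held counting error only and planted changes in genes of at least 25 CPM. Pairs of real runs, each of lower depth, put 105 to 194 genes of library 3 and 187 to 260 of library 4 at least 4-fold apart. The simulated rates thus check the calling and do not measure the noise of real libraries.

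**Figure D5:**
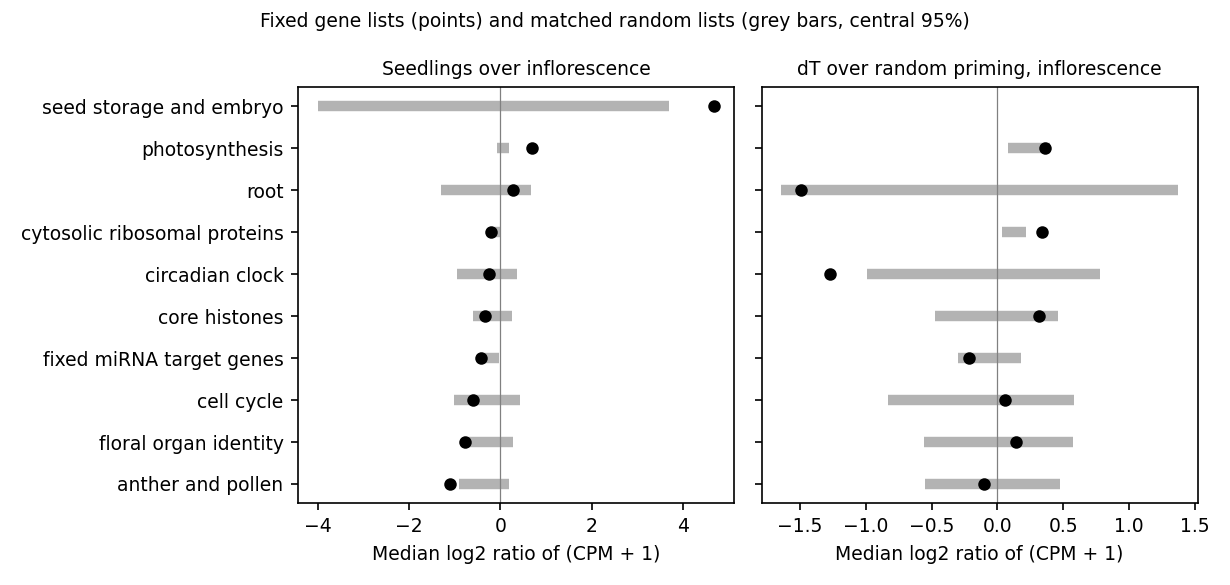
Median log2 ratio (x axis) of the fixed gene lists (y axis) as points, with grey bars for the central 95% of matched random lists, for seedlings over inflorescence (left) and dT over random priming in inflorescence (right). The photosynthesis list (0.68) lies right of its bar and the floral organ (-0.79) and anther and pollen (-1.11) lists left of theirs for seedlings, where size factors, which raise all genes alike, put the medians of the ribosomal protein and clock lists at 0.076 and 0.03, at percentiles 0.01 and 50.5.

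The 2 inflorescence libraries set dT priming against random priming in 1 tissue, but they also differ in amplification (as a pool in library 2, by primer extension in library 3), so the differences are those between the preparations. Genes higher with dT priming were of mixed function: AT1G68440 (log2 ratio 3.71, 2.97 to 5.48 over run pairs), AT5G35480 (3.68, 2.89 to 6.06), the iron superoxide dismutase FSD1 (3.65, 2.93 to 7.15), AT3G47160 (3.45), the glutathione S-transferase GSTF2 (3.43), AT1G14890 (3.34), MYBL2, a repressor of anthocyanin synthesis (3.18), AT1G54850 (3.08), AT5G50030 (2.96), ACL (2.75), AT1G73090 (2.55) and AT1G14345 (2.54). Each had between 43 and 103 tags in library 2 and between 5 and 18 in library 3.

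Several of the 12 genes with the largest ratios lower with dT priming had most of their library 3 tags at 1 start. AT1G04590, a pentatricopeptide repeat protein (chromosome 1, 1258556 to 1261470), had 61441 tags with random priming and 56 with dT, a log2 ratio of -9.20 (-9.52 to -8.91), and 99.9% of the former lay at 1 start. AT1G19540 (-7.21) had 99.9%, AUR1 (-6.77) 98.1% and AT4G12750 (-4.62) 98.4% at 1 start, and AT4G09035, at least 45.1-fold lower, had all of its 249 tags there. AT2G01008 (-7.81) had 63.1% and AT3G19020 (-4.63) 81.2% at 1 start. UGT75B1 (-4.59) and the homeobox gene HB23 (-4.08) had 60% and 84.5% of their library 3 tags after TCCAAC. Tags were spread over 139, 34 and 36 starts for AT3G24480 (1 tag against 393, 214-fold lower, 38.1 to 8462), AT2G31141 (1 against 93, 50.6-fold, 8.86 to 2019) and AT2G23910 (1 against 88, 47.9-fold, 8.37 to 1911).

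Cytosolic ribosomal proteins were higher with dT priming, with a median log2 ratio of 0.34 and 207 of 282 members higher (percentile 100), from AT5G11750 and AT1G57540 (at least 6.13-fold and 5.52-fold higher) to AT3G01170 (-2.25) and AT5G63070 (at least 3.81-fold lower). Circadian clock genes were lower, with a median of -1.27 and 5 of 7 members lower (percentile 0.470). LHY (-1.65) and CCA1 (-1.56) lay lowest and GI (0.80) highest, and with each start counted once the median was -0.11. Photosynthesis genes had 0.36 with 44 of 50 higher (percentile 92.6), from PSAD-2 (1.44) and PSAD-1 (1.12) to PSAN (-1.59), of whose library 3 tags 71.4% followed TCCAAC, and FNR1 (-1.76). Core histones had 0.31 (percentile 89.4), with AT1G21920 (1.16) and HTA11 (0.77) highest, the former of the SET7/9 family. The miRNA target genes had -0.22 with 51 of 86 lower (percentile 9.68), from FAMT (at least 5.52-fold higher) and NF-YA9 (1.66) to ARF17 (-2.26) and NF-YA10 (-2.79). The floral organ list had 0.14 (percentile 59.6), with SUP (13 tags against 1, 23.9-fold higher, 3.59 to 1016) and STK (1.11) highest and LFY (-1.52) lowest. The anther and pollen list had -0.11 (percentile 34.6), from AGP6 (0.98) to CYP703A2 (-1.85). The cell cycle list had 0.06 (percentile 67.7), and 3 measured root genes had -1.49 (percentile 4.17). No seed storage or meiosis gene was measured.

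Over 13160 measured genes, 466 were at least 4-fold higher and 740 at least 4-fold lower with dT priming, 404 and 707 of them in the same direction in all 12 pairs of runs. The correlation of log2 CPM across genes was 0.739, against 0.751 to 0.875 between runs of library 2 and 0.886 to 0.910 between runs of library 3. The counts were 142 and 330 at a minimum of 25 CPM, and 96 and 243 with a pseudocount of 5. The excess of lower genes turned over the last 500 nt of transcripts (1147 higher and 596 lower) and with each start counted once (676 and 602). In simulated libraries 94.0% of genes changed 6-fold and 100% of those changed 12-fold were recovered, with 11 of 12232 unchanged genes called. This simulation too held counting error only. Pairs of real runs of library 2, each of lower depth, put 246 to 937 genes at least 4-fold apart.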

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

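The counts on miRNA precursors were made after the results of the report had been seen, and no explanation of them was tested. Tags that started exactly at the 5′ end of an annotated miRNA on its precursor transcript, a position that no comparison of the report used, numbered 85 in library 2, 1473 in library 3 and 656 in seedlings. They are listed because they lay outside the comparisons and above the limit that a count of 0 allows, which any position with more than 3 tags passes, with 65.1, 293 and 166.4 CPM of all tags against 2.299, 0.598 and 0.761. These tags made up 59.4% (exact 95% interval 50.9% to 67.6%), 81.5% (79.6% to 83.2%) and 70.1% (67.0% to 73.0%) of the tags in a window of 46 nt around the 5′ end, and the next highest position of the window held 18, 94 and 85 tags. Of 40 families with an annotated precursor, 13, 21 and 18 had such tags.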

How the results depend on the processing

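Chosen after the data were seen were the alternatives without starts tagged in both libraries, without starts that follow TCCAAC, without guides that repeat 3 nt, and with the repeated runs. Of 288 alternatives other than leaving out runs, 214 changed no result beyond its limits, 6 ended and 11 made a call, 56 moved a value and 1 changed its sign. The cause of the changes below was not tested except where stated.

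Opposite guide nucleotide 9 the fixed sites at the transcript maximum numbered 0, 4 and 0 in libraries 2, 3 and 4, and opposite nucleotide 11 they numbered 0, 1 and 1, positions off the slice position by construction. A window of 3 nt raised the slice share of library 3 to 10.1%.

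The ratio of search matches to shuffled guides moved most. In libraries 2, 3 and 4 it was 48.8, 96.6 and 92.6 with tags of 1 gene only, 4286, 1855 and 2450.0 at a score of at most 3, 159, 54.4 and 135.1 at a score of at most 5, and 114, 112 and 189 at any position with at least 2 tags. With dinucleotides kept and 1 guide per family it was 10.98, 46.6 and 39.9. Without guides that repeat 3 nt it was 53.1, 100 and 119, and 44.7, 83.8 and 100 with dinucleotides kept as well. At a minimum of 5 tags it was 283 in library 2. Leaving out 1 run gave 170 to 1120 in library 2, where the lowest was without run 1 and the highest without run 2, and 770 to 1140 in library 4, where run 6 left out gave the highest and run 15 left out 1070. Few matches of shuffled guides stand behind each ratio, which limits its precision.

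The median tag position in libraries 2, 3 and 4 was 87.9%, 72.5% and 77.8% with each gene weighing the same, 81.9%, 76.8% and 79.7% on transcripts of 1000 to 2000 nt, and 84.2%, 65.6% and 68.7% with each start counted once. Without the 1% of genes with most tags it was 85.6% in library 2 and 74.4% in library 3. Under each of these, library 2 kept the highest and library 3 the lowest median.

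For seedlings against inflorescence, genes higher and lower numbered 607 and 1624 at 5 CPM, 171 and 292 at 25 CPM, 185 and 261 with a pseudocount of 5, 2092 and 3257 without starts tagged in both libraries, and 1146 and 1235 with each start counted once. For dT against random priming they were 142 and 330 at 25 CPM, 96 and 243 with a pseudocount of 5, and 899 and 1319 without shared starts, and 834 were higher at 5 CPM. Over the last 500 nt they were 1147 and 596, and with each start counted once 676 and 602, which turns the excess of lower genes. The CPM minimum changes how many genes are measured, the pseudocount shrinks ratios of low counts, and leaving out shared starts keeps only starts with tags in 1 library, so that ratios grow by construction and larger values under it show no stronger difference. Leaving out 1 run gave 373 to 411 genes higher and 917 to 1034 lower in seedlings, and 478 to 604 higher and 719 to 1011 lower with dT priming.

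Among lists, ribosomal proteins in seedlings had 0.076 with size factors, a change of sign from a scaling that raises all genes alike, and at percentile 0.01 they stayed below the random lists (0.15 to 0.29). Cell cycle genes passed the percentile limit with each start counted once (-1.24), miRNA targets with that choice (-0.44) and without shared starts (-0.84), and root genes at 1 CPM (0.80), with each start counted once (2.04) and without shared starts (2.42). For dT priming, the clock list lost its call with each start counted once (-0.11). Calls were made for core histones with each start counted once (0.66) and without shared starts (0.59), miRNA targets with each start counted once (-0.31), photosynthesis without shared starts (0.93) and root genes at 1 CPM (-1.34).

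Depth limits the sites with few slice tags and genes near 10 CPM, for which a count of 0 allows 3.53, 1.92 and 2.22 CPM in libraries 2, 3 and 4.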

Other observations

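The tests of floral gene tags, of starts after TCCAAC, and those of few starts and of lost junction tags were chosen after the results were seen, and so were the counts per miRNA family. On the precursors, tags at the miRNA 5′ end were fewer in seedlings over all families (293 CPM of all tags in library 3 and 166.4 in seedlings). The miR166 family, first in both random primed libraries and directed at class III HD-ZIP genes, had 661 such tags in the random primed inflorescence library and 227 in seedlings, 2.29-fold fewer relative to all tags (95% interval 1.96 to 2.67). The miR162 family, whose target is DCL1, had 190 against 35 (4.26-fold fewer, 2.96 to 6.30), and the miR167 family, which targets auxin response factors, 128 against 34 (2.96-fold fewer, 2.01 to 4.45). For miR162 the window held 371 tags in library 3 and 146 in seedlings, of which 88 and 63 lay after the miRNA 3′ end. For miR173, which cleaves TAS1 and TAS2 transcripts, there were 30 against 2 (11.8-fold fewer, 2.99 to 101.7). The miR156 family of the juvenile phase went the other way, with 74 against 174 (2.99-fold more in seedlings, 2.27 to 3.99). The copper-responsive families miR408 and miR398 had 12 and 8 such tags in seedlings and 0 in both inflorescence libraries, and those of miR408 were 12 of 119 tags in the window. With 1 library per tissue these ratios cover counting error only.

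Tags of coding sequences gathered 26 to 30 nt upstream of exon junctions, near the 5′ edge of the stretch that exon junction complexes cover. Over 95838 junctions this window held 2.05 times the tags of the windows 10 nt either side in library 2, 2.17 times in library 3 and 2.31 times in seedlings. A base preference at tag ends, a few heavily tagged starts, and the loss of tags that cross a junction were each argued against. The ratios kept their size when weighted by the bases around the tag start (2.299 in seedlings), with each start counted once (at least 1.97) and against the window 36 to 40 nt upstream, whose tags cross no junction (at least 2.04). Protection of decaying RNA by exon junction complexes, predicted before the ratio of 2.31 was seen, may account for the peak, which stays a hypothesis because no sample lacked these complexes.

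Floral genes had many tags in the seedling library, and 97.7% of the 3576 seedling tags of the floral organ and the anther and pollen lists lay at starts that library 3 had tagged too. That share was 28.7 percentage points above the share at starts of library 2, but over all genes the shares were 78.6% and 53.4%, so this gap alone does not set floral genes apart. The share at starts of library 3 was also high for cell cycle genes (97.1%), core histones (91.7%) and cytosolic ribosomal proteins (91.0%). Of the 1865 seedling tags of the cell cycle list, however, 1700 lay at 1 start of AUR1. Of its other tags, 54 lay at starts without a library 3 tag, so its high share rests on that start. The share lay between 0% and 84.6% for the other lists. Transcripts of these genes in the seedlings as the main source were argued against, since a member had a median of 1.23% of its seedling tags at starts without a library 3 tag, against 26.6% (16.98% to 41.3%) in matched genes. A single mislabelled run was argued against by the even level of these genes over the 4 seedling runs, the highest being 1.08 times the lowest. Molecules shared between the random primed libraries, from a mixture at some step of preparation, may be a candidate explanation, since starts that random priming favours would be shared by the matched genes alike. A carry-over of library 3 tags in proportion to their number would give seedling tags at light and heavy starts alike. Of the starts of these lists with at least 10 library 3 tags 82.9% had a seedling tag (150 of 181), but 3.79% of those with at most 4 (35 of 923), and seedling tags per library 3 tag were 0.150 times as many at the latter (95% interval over members 0.0885 to 0.245). That interval lay wholly below an equal rate, which argues against a carry-over in strict proportion for these lists. The limit set for excluding such a carry-over lay within the interval, so by that limit it was not excluded. Over all nuclear protein-coding genes 96.0% of such heavy starts and 9.51% of such light starts had a seedling tag. Seedling tags per library 3 tag there were 0.958 and 0.225, so the contrast is not particular to floral genes. LAP5, AMS, SEP4 and SHP2, without a seedling tag, had at most 7 library 3 tags at a start. Outside the lists, E13L3 had 0 seedling tags against 201, and the start of CSLA01 with 400 library 3 tags had none. Such a heavy start without a seedling tag was rare. Of 93 starts with at least 300 library 3 tags over all genes, 92 had a seedling tag and 66 a library 2 tag. At those with a seedling tag, the median log2 ratio of seedlings to library 3, scaled to each library's tags, was 0.35 (quartiles 0.17 and 0.45). How molecules came to be shared was not tested, and if they were, the seedling slice shares and all ratios of seedlings to inflorescence would include them.

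Starts that follow TCCAAC, the end of the 5′ adapter, in the transcript held 2.65% of the tags of library 3 and 2.16% of those of library 4, 85.2 and 71.5 times their share under even spread. Library 2, of the same tissue as library 3, had 0.247% of its tags there, 8.67 times that share. RNA ends at this sequence in inflorescence were argued against, because the excess in library 3 was 9.82 times that in library 2. Among starts after TCCAAC, those that the next 2 adapter bases also preceded were at least 2.33 times as frequent as such positions in libraries 3 and 4, so priming by the adapter's end within transcripts may be a candidate explanation. The rule for tags checked only GTTGGA, the reverse complement of TCCAAC. A read that held GTTGGA from the transcript and not from the adapter would pass alike, and this was not tested. CYSC1 alone held 874 of the 2080 such tags of library 2, and its share was alike in libraries 2, 3 and 4 (94.7%, 92.4% and 94.5% of its tags), so RNA ends stay open for this gene.

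The second codon position led in all 3 libraries, but by at most 0.904 percentage points over the share expected of the bases at tag ends, and tags 16 to 17 nt upstream of stop codons were at most 1.097 times the flanking level. Genes lower with dT priming had transcripts 1.29 times as long in median as genes higher with it (1939 against 1507 nt), a ratio between the limits set beforehand for and against an effect of length. Genes lower and higher in seedlings, where both libraries were random primed, differed by the same ratio (2013 against 1557 nt), so the ratio is not particular to dT priming, and whether it has a part stays open.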
